A study of Rattus norvegicus with 5 samples.

How the data were processed

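RNA was measured in 5 samples of sorted blood cells on the Applied Biosystems rat genome survey microarray, a 1-colour array of 60-mer probes. Per the labels' protocols, red cells were lysed, cells bearing MHC class II or CD3 were removed with antibody-coated beads, cells stained for CD80 and CD86 were collected magnetically, and digoxigenin-labelled cRNA was made from amplified total RNA. Groups were taken from the sample titles: 3 tolerant and 2 syngeneic samples, all at day 100. The deposited raw table holds the intensity of each probe on each array on a linear scale, not normalized between arrays; whether a local background was subtracted, the scanner software and any detection flags are not given in the sources used here. The deposited series matrix holds log2 values that the authors had quantile normalized: set against the quantile-normalised raw intensities they differed by at most 0.000102, with a Spearman correlation of 1 on each array, no centring per gene, and a median of 9.41 on each array. The software of that step is not given in the sources used here. No scan date, slide or batch label was used, so batches could not be tested.

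Intensities were quantile normalized, floored at the 10th percentile of all values (log2 8.29) and put on the log2 scale; 1 probe with a missing signal was left out. Probes with a mean log2 signal at or above the median of all probes (9.40) were tested, 13428 in all, with the linear model and moderated variance of limma 3.58.1 in R 4.3.3 (prior degrees of freedom 3.19), and p-values were adjusted by the Benjamini-Hochberg method; every adjusted p of a gene or list comes from these tools. Differences are tolerant minus syngeneic on the log2 scale. The number of arrays limits the precision. Probe names come from the platform's annotation in GEO, which is old: 6104 probes have 1 gene symbol, 70 have several and 20683 are not listed, and the latter are unnamed here rather than without a gene. Of the Entrez identifiers, 6081 matched the RefSeq gene table and 0 symbols changed. Only 3487 of the tested probes are named, for 3435 genes, so gene lists cover the named part. A gene with several probes is given by the probe with the highest mean; for Ccr1 and Gapdh a second probe was also tested, and the second Gapdh probe gave 1.02 where the first gave 0.12.

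The files hold no detection call. A background level was therefore set, after the data had been seen, at the 95th percentile of 464 olfactory receptor probes on each array (log2 11.20, 10.72 and 10.71 on tolerant arrays 1, 2 and 3, and 10.73 and 10.80 on syngeneic arrays 1 and 2). Where every array of 1 group lay at or below it, the fold is given as a lower bound: the mean of the brighter group against the mean of, per array, the higher of the background level and the probe's own value. A log2 difference printed for such a gene is the fitted value and measures no more than the bound. No fold is given where both groups were at background, and where only some arrays of a group lay above it the difference is partly measured against background. For a list, the median with genes at their bounds sets a gene at background in both groups to 0.

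Gene lists for functions of suppressor cells, immune pathways, housekeeping processes, and markers of the other blood cell types that a sort could hold were fixed before the data were examined, 31 in all; 30 had at least 5 tested members. Each was tested with camera in limma with the preset correlation of 0.01, again with an estimated correlation, and with fry, whose PValue asks whether the genes of a list move on balance one way and whose mixed PValue asks for change in either direction. Camera called 7 lists, 5 lower and 2 higher; 0 were called with an estimated correlation, 4 by fry and 4 by its mixed test. Counts within a list are given over all genes tested and adjusted over the list alone. The rule for named genes was also fixed: the 10 largest rises and falls past the threshold with full separation of the groups, filled to 8 in each direction by the smallest p among differences of at least 1 on the log2 scale; the 2 members of each list with the smallest p and any past the threshold; and a set always named, with Ccl5 (which this laboratory is known to have followed up), Ccr1, Ccr3, effectors of suppressor cells, antigens of the sort and depletion, Klrb1a, Itgam, Actb and Gapdh. No probe is named for Cd274, Cd3e and RT1-Ba, and 1 gene of the set is not reported here. Genes named outside the rule are said to be so.

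The tests were checked on simulated data of the size of the real table, with 50 of 13428 probes changed at each of 4 sizes. Recovery was 0%, 0%, 58% and 88% for differences of 1, 2, 4 and 6 on the log2 scale, with 1 false call, and 5.13% of unchanged probes had an unadjusted p under 0.05. For lists, a simulated shift of -2 in the NK cell list was called by camera with the preset correlation, and 0 of 26 lists without shared members were. With an estimated correlation camera gave the shifted list an adjusted p of 0.156, so this setting missed a simulated shift. Its lack of calls in the real data therefore does not show that no list moved. Simulated genes were drawn independently. In the real data the estimated correlation was 0.79 for MHC class II, 0.72 for B cell markers and 0.004 for NK cell markers. The 0 calls among the 26 simulated lists therefore do not show how often lists of correlated genes are falsely called. Alternatives covered other scalings between arrays, the authors' values, floors, filters, variance models, array weights, the replicate number as a block, leaving out each array, and other thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.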

Results

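Gene expression was measured in rat blood cells enriched for myeloid-derived suppressor cells (MDSCs), a mixed population of immature myeloid cells that can restrain T cell responses. The cells came from LEW.1A rats 100 days after kidney transplantation. Tolerant recipients had accepted a LEW.1W kidney, mismatched for the MHC, after treatment with JJ319, an antibody against the T cell costimulatory receptor CD28. Syngeneic recipients carried a LEW.1A kidney, which is not rejected, and had no mismatch to tolerate. The sort removed cells bearing MHC class II or CD3, the T cell receptor complex, and then kept cells bearing CD80 or CD86, ligands of CD28. There were 3 tolerant arrays and 2 syngeneic arrays, whereas the series' design text counts 3 recipients in each group. Each array was read as 1 chemiluminescent signal per probe for 26857 probes, of which 1 had a missing signal and was left out. The median signal was 563, 600 and 757 on tolerant arrays 1, 2 and 3, and 798 and 676 on syngeneic arrays 1 and 2. Between 22.6% and 27.2% of probes on each array lay above a background level set from olfactory receptor genes, which blood cells should not express. No label ties an array to an individual animal, so p-values measure only the spread between these samples, which may be technical.

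The comparison asked which genes differ between suppressor cells of recipients that tolerate an allograft and those of recipients that had nothing to tolerate. Among probes past the threshold was Ccl5 (RANTES), a chemokine that attracts T cells, natural killer (NK) cells and monocytes. Its log2 signal was 12.41 ± 0.64 (SD, n = 3) in tolerant and 19.72 ± 0.21 (SD, n = 2) in syngeneic cells, a difference of -7.30 (SE 0.51), or 158-fold lower (limma, Benjamini-Hochberg adjusted p = 0.036). Both groups were above background for Ccl5 on all arrays. Gzmk, a granule protease of cytotoxic lymphocytes, fell by 6.74 (SE 0.54, adjusted p = 0.040). Klrd1 (CD94), a lectin-like NK receptor, fell by 6.29 (SE 0.41, adjusted p = 0.036), and Klre1, another receptor of the same family, fell by 4.95 (SE 0.41, adjusted p = 0.040). Cd5, a surface glycoprotein of T cells and some B cells, fell by 5.44 (SE 0.46, adjusted p = 0.040). These 4 genes were at background on all 3 tolerant arrays, so their folds are lower bounds: at least 31.3-fold lower for Gzmk, 16.5-fold for Klrd1, 9.08-fold for Cd5 and 6.80-fold for Klre1.

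Of 13428 probes tested, 6 passed an adjusted p of 0.05 with limma, all of them lower in tolerant cells, and 0 were higher. An unadjusted p under 0.05 was reached by 721 probes, of which 454 were lower and 267 higher, against 671 expected by chance. The last of the 6 is an unnamed probe (22024243, named here after its value was seen) that fell by 5.91 (SE 0.46, adjusted p = 0.040), at least 37.8-fold. For all 6, each tolerant value lay below both syngeneic values. Of the named genes, the next by the rule were lower without passing: Nkg7, a granule membrane protein of NK and T cells, by a log2 difference of -6.37 (adjusted p = 0.061), Dgat2, an enzyme of triglyceride synthesis, by -3.59 (adjusted p = 0.122), and Lat, an adaptor of T cell receptor signalling, by -5.39 (adjusted p = 0.132). All 3 were at background in tolerant cells and were at least 57.1-fold, 3.33-fold and 13.7-fold lower. The count of 6 fell to 0 when any array other than syngeneic 1 was left out and was 91, 38 lower and 53 higher, when syngeneic 1 was left out, although the 5 named genes kept their direction in every such fit. Differences of this kind are near the limit of the design: of simulated differences of 2 on the log2 scale 0% were recovered, and of 4 and 6, 58% and 88%.

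**Figure D1:**
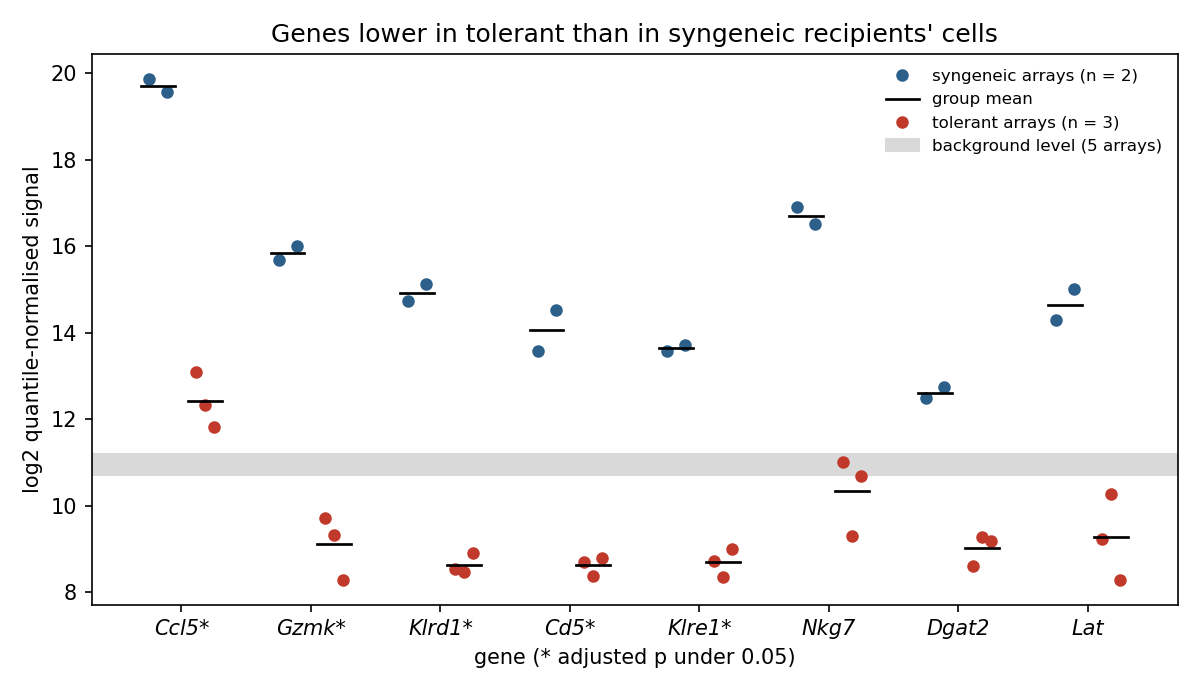
Log2 quantile-normalised signal (y axis) of the 8 named genes with the smallest p among those lower in tolerant cells (x axis), each point 1 array (syngeneic n = 2, tolerant n = 3) and each bar a group mean; the grey band spans the background levels of the 5 arrays. Ccl5 lies above the band in both groups, with tolerant values of 13.10, 12.32 and 11.82, while the other genes lie in or below it on the tolerant arrays.

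Markers of NK cells were lower as a group. All 15 tested members of the fixed NK cell list had a negative difference, with a median of -2.53 (camera in limma, adjusted p = 1.3e-17 with the preset correlation; adjusted p = 0.073 with an estimated correlation). Over all genes 2 of the 15 fell, Klrd1 and Klre1, and 12 fell when adjusted over the list alone. Among the 12 were Gzmb and Gzma, granzymes that trigger death of target cells (-3.23 and -2.99), and Il2rb, a subunit of the IL-2 and IL-15 receptors (-2.65); these 3 were chosen after their values were seen, were at background in tolerant cells, and were at least 1.93-fold, 2.24-fold and 2.02-fold lower (Il2rb 1.04-fold without syngeneic 1 and 3.91-fold without syngeneic 2). Klrb1a (NKR-P1A), the classical rat NK marker, differed by -1.52 (SE 0.58) and was above background on only 1 tolerant array. The fall was not uniform. Klrk1, another member, named after its value was seen, differed by only -0.04 (SE 0.93). It was above background on all 3 tolerant arrays and 1 syngeneic array, and differed by 1.38 without syngeneic 1 and -1.47 without syngeneic 2. Because 10 of the 15 were at background in tolerant cells, the list's median with such genes set to their bounds was -1.01.

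T cell markers fell too, although CD3-bearing cells had been depleted from both groups. Of 16 tested members 13 were lower, with a median of -2.27 (adjusted p = 1.6e-10; adjusted p = 0.073 with an estimated correlation; -0.88 with genes at their bounds). Cd5 fell over all genes and 9 members fell when adjusted over the list alone, Cd5, Lat and Cd3d among them. Cd3d, a chain of the CD3 complex, was 10.83 ± 0.35 (SD, n = 3) in tolerant and 14.32 ± 0.62 (SD, n = 2) in syngeneic cells, a difference of -3.49 (adjusted p = 0.186), measured largely against background, since only 1 tolerant array lay above it. Cd8b and Gata3, named after their values were seen, differed by -2.71 and -2.76 (Gata3, at background in tolerant cells, at least 2.99-fold). The cytotoxic granule list, which shares 5 members with the NK list, had a median of -2.19 over 11 genes (adjusted p = 5.5e-09; adjusted p = 0.073 with an estimated correlation; -0.74 with genes at their bounds). In it 9 genes were lower, Gzmk fell over all genes, and 6 fell when adjusted over the list alone. The 6 members outside the NK list had a median of -0.71. With fry, which tests whether a list's genes move on balance one way, the NK, T cell, cytotoxic and neutrophil lists passed (adjusted p = 0.006, 0.005, 0.015 and 0.047), and no other list did.

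**Figure D2:**
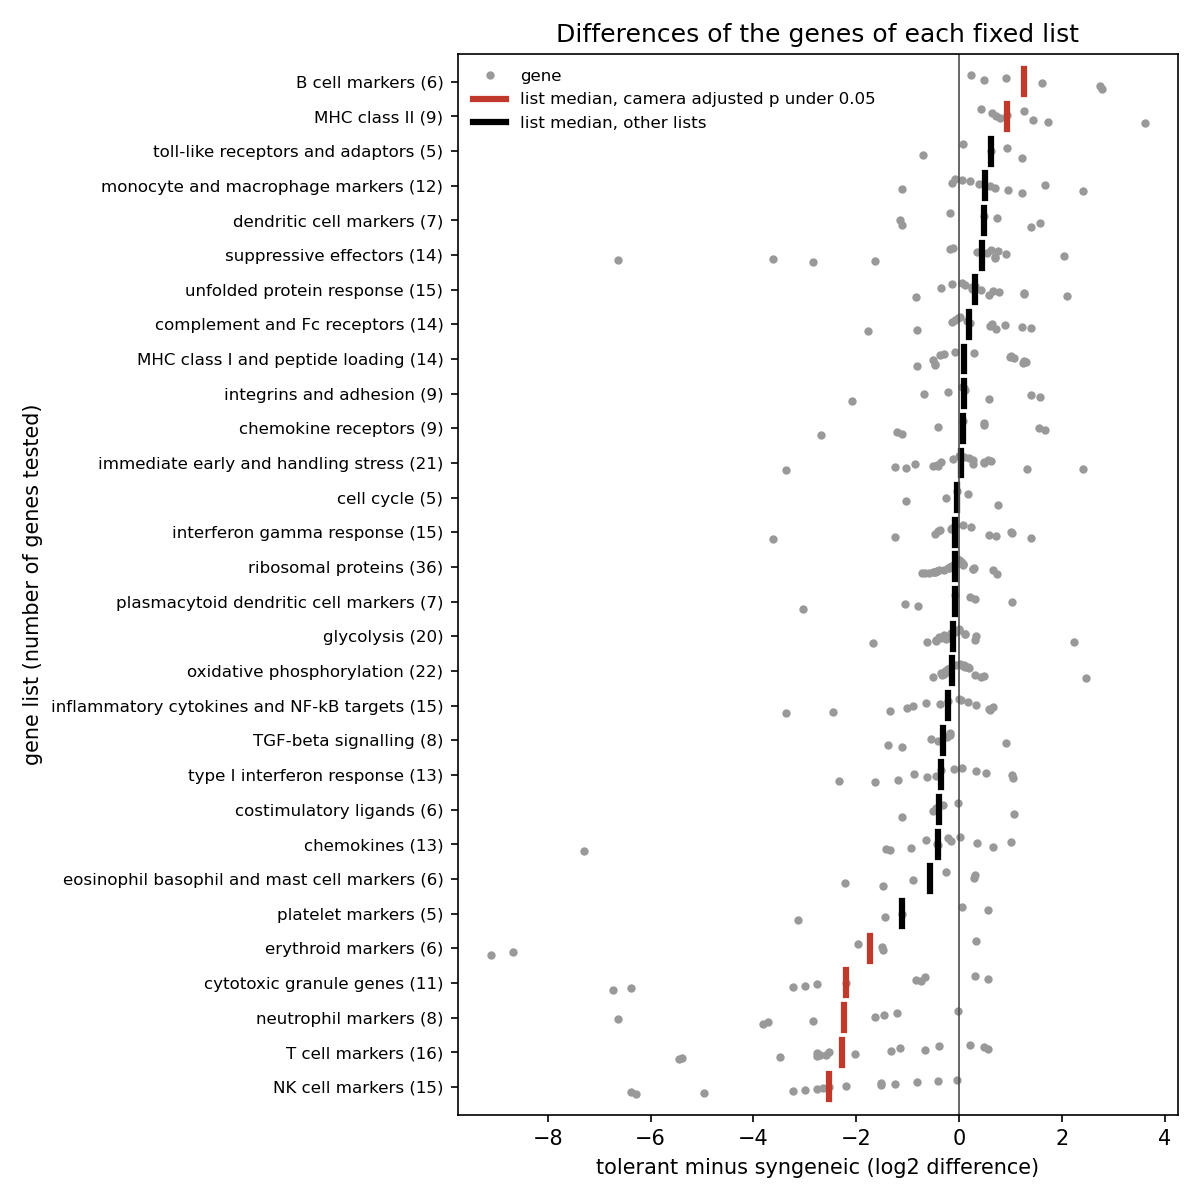
Log2 difference, tolerant minus syngeneic (x axis), of each gene (grey points) in the 30 tested gene lists (y axis, number of genes tested in parentheses); bars are list medians, red where camera with the preset correlation gave an adjusted p under 0.05. The NK cell, T cell, neutrophil and cytotoxic lists have medians from -2.53 to -2.19, and the B cell and MHC class II lists lie at the other end, at 1.26 and 0.94.

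Neutrophil markers were also lower in tolerant cells. All 8 tested members had negative differences, with a median of -2.23 (adjusted p = 7.0e-07; adjusted p = 0.118 with an estimated correlation; -1.53 with genes at their bounds). None passed over all genes, and 5 fell when adjusted over the list alone. These included Pglyrp1, a bactericidal granule protein (-3.80, SE 0.61, with only 1 tolerant array above background), Il1r2, the decoy receptor for IL-1 (at background in tolerant cells and at least 3.61-fold lower; 8.44-fold without syngeneic 1 and 1.54-fold without syngeneic 2), and S100a8, a calcium-binding protein abundant in neutrophils and monocytes (-2.84, SE 0.67). S100a8 was above background on all arrays, at 15.92 ± 0.67 (SD, n = 3) in tolerant and 18.75 ± 1.18 (SD, n = 2) in syngeneic cells.

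The erythroid list fell with a median of -1.74 over 6 genes, 5 of them lower (adjusted p = 3.0e-04; adjusted p = 0.623 with an estimated correlation; the median was the same with genes at their bounds). None passed over all genes and 3 passed when adjusted over the list alone: Hbb, Hbb-b1 and Gata1, an erythroid transcription factor. Gata1 was at background on all arrays of both groups, so no change in it is measured. The probes for the beta globins Hbb and Hbb-b1, close paralogs that may cross-hybridise, were at background on all 3 tolerant arrays. In syngeneic cells Hbb was at 14.49 and 20.30, so it was at least 91.9-fold lower in tolerant cells, and Hbb-b1 was at least 84.4-fold lower (adjusted p = 0.292 for each). Without syngeneic 2 these bounds were 12.3-fold and 12.7-fold, and without syngeneic 1 they were 686-fold and 560-fold. Syngeneic 2, the array with the higher globin signals, also stood apart over all probes. It correlated at 0.79 to 0.81 with the other 4 arrays, which correlated at 0.88 to 0.93 with each other. Some genes above background on the other 4 arrays were at background on syngeneic 2. Atp5f1b was at 8.45, against 14.46 on syngeneic 1, and Hsp90b1 at 8.77 against 13.81. The second Gapdh probe was at 12.94 against 16.86, but the first was at 17.76 against 18.08. Whether this array or its RNA was sound was not tested. Without syngeneic 2 the erythroid median was -0.36, and without syngeneic 1 it was -3.98.

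In the other direction, genes of MHC class II, which presents antigen to CD4 T cells, rose as a list. All 9 tested members were higher, with a median of 0.94 (adjusted p = 2.0e-04; adjusted p = 0.623 with an estimated correlation; 0.80 with genes at their bounds). None rose over all genes or when adjusted over the list alone. RT1-DOa, a chain of the class II chaperone DO, differed by 3.61 (SE 0.97, adjusted p = 0.667) and was at background in syngeneic cells, and RT1-Da, a classical class II chain and a target of the depletion, by 1.45 (SE 0.80; 0.42 without syngeneic 2 and 2.48 without syngeneic 1). Although class II-bearing cells had been depleted, RT1-Da was above background on all arrays. Its signal was 17.65 ± 0.88 (SD, n = 3) in tolerant and 16.20 ± 1.46 (SD, n = 2) in syngeneic cells. The list median was 0.42 without syngeneic 2, 0.62 without tolerant 2 and 1.61 without syngeneic 1. By array, tolerant 1 at -0.055 lay below syngeneic 1 at -0.043, while tolerant 2 was at 1.18 and syngeneic 2 at -1.23. The class II list thus did not part the groups. The B cell list moved with it: all 6 tested members were higher, with a median of 1.26 (adjusted p = 0.008; adjusted p = 0.623 with an estimated correlation; 0.81 with genes at their bounds), and again none passed over all genes or over the list alone. Fcer2 (CD23), at background in syngeneic cells, was at least 1.65-fold higher (2.82-fold without tolerant 1 and 1.10-fold without tolerant 2), and Cd79b, a chain of the B cell receptor, differed by 2.75 (SE 0.92). The B cell call rested on single arrays, since its median was 0.14 (adjusted p = 0.792) without syngeneic 1, 0.67 (adjusted p = 0.081) without tolerant 2 and 2.52 without syngeneic 2.

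**Figure D3:**
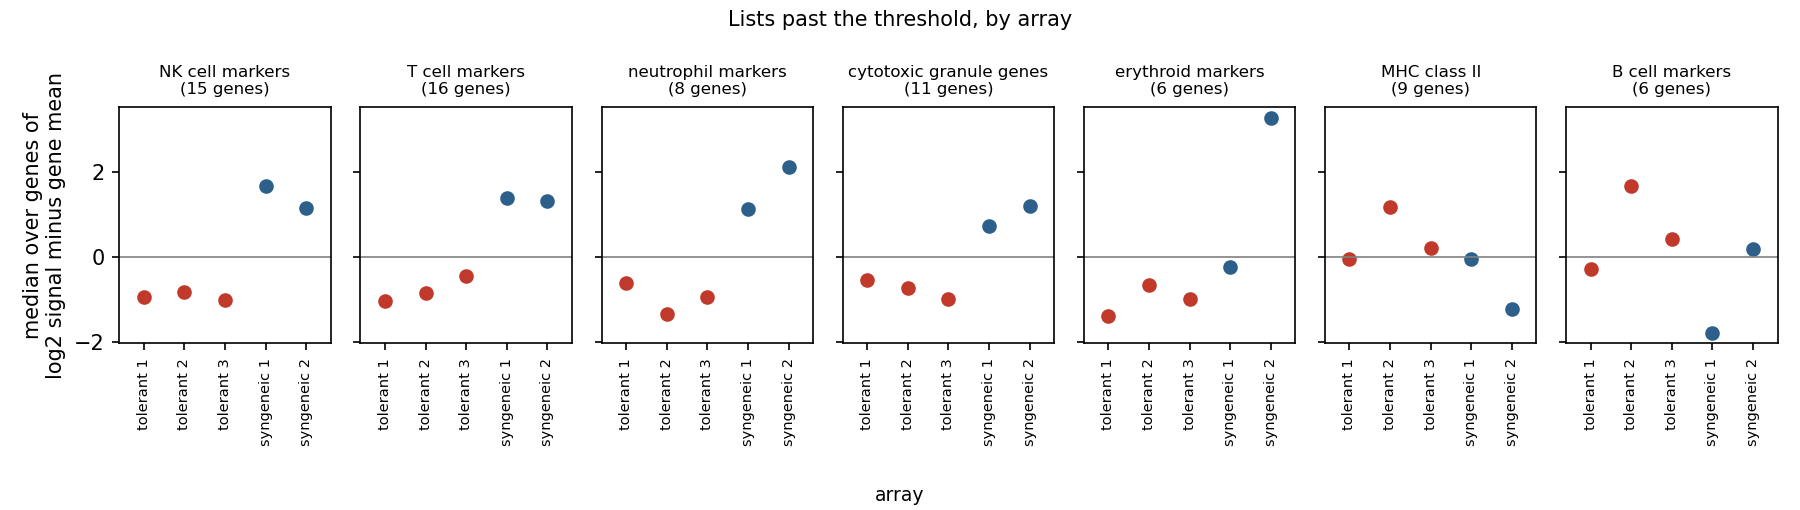
Median over the genes of each list of the log2 signal minus that gene's mean over the 5 arrays (y axis), by array (x axis), for the 7 lists past the threshold; red points are tolerant and blue points syngeneic arrays. The NK cell, T cell, cytotoxic, neutrophil and erythroid lists part every tolerant from every syngeneic array. In the erythroid list the size comes mostly from syngeneic 2 at 3.29, against -0.24 on syngeneic 1. For B cell markers tolerant 1 at -0.28 lies below syngeneic 2 at 0.20. For MHC class II tolerant 1 at -0.055 lies below syngeneic 1 at -0.043.

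The suppressive effectors of MDSCs were not called as a list by camera. Of 14 tested genes 6 were lower and 8 higher, with a median of 0.45 and a mean of -0.60 (adjusted p = 0.798). None passed, over all genes or over the list alone. The 4 members with an unadjusted p under 0.05 in limma, S100a8, S100a9, Lgals1 and Nos2, were all lower. By array the list median was 0.59 on syngeneic 1, -0.42 on syngeneic 2 and from -0.05 to 0.37 on tolerant arrays. Nos2, the inducible nitric oxide synthase through which rodent MDSCs can block T cells, was 10.02 ± 1.84 (SD, n = 3) in tolerant and 13.63 ± 1.34 (SD, n = 2) in syngeneic cells (adjusted p = 0.821), with only 1 tolerant array above background. Hmox1, haem oxygenase 1, differed by -0.18 (SE 0.49) and Lgals1, galectin 1, by -1.62 (SE 0.42, adjusted p = 0.631). Arg1 and Ido1, enzymes that deplete arginine and tryptophan, were below the signal filter, and no probe is named for Cd274 (PD-L1) in the annotation used here. Of the sorted antigens, Cd86 differed by 1.08 (SE 0.84), with only 2 tolerant arrays and 1 syngeneic array above background, and Cd80 was below the filter. The myeloid integrin Itgam (CD11b) differed by 1.39 (SE 1.05) and was above background on only 1 syngeneic array. The housekeeping genes Actb and Gapdh differed by 0.64 (SE 0.54) and 0.12 (SE 0.41). For Cd86, Itgam, Actb and Gapdh the sign turned without syngeneic 2, for Hmox1 without tolerant 2 or syngeneic 1, and for Gapdh also under median scaling, without normalization and without tolerant 3.

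Ccl5 was the 1 chemokine to fall over all genes and when adjusted over the list alone. With Ccl5 among its 13 genes, 9 of them lower and 4 higher, the chemokine list had a median of -0.41 (camera, adjusted p = 0.078). Fry's mixed test, which asks for change in either direction, passed (adjusted p = 0.001). Neither test was run without Ccl5, so that pass does not show that other chemokines changed. Ccl4, a related CC chemokine, differed by -1.35 (SE 0.46, adjusted p = 0.867). Ccr1, a receptor that binds Ccl5, differed by -0.40 (SE 0.49) (0.15 without syngeneic 2) and by -0.92 on a second probe, and Ccr3 was below the filter. Cxcr3, a chemokine receptor of activated T and NK cells, differed by -2.68 (SE 0.64, adjusted p = 0.563) and was above background on only 1 tolerant array. Monocyte and macrophage markers had a median of 0.50 over 12 genes (adjusted p = 0.080), with Cd14, a coreceptor for bacterial lipopolysaccharide, at 1.22 (SE 0.51) and the nuclear receptor Nr4a1 at 2.42 (SE 1.10). Without syngeneic 2 these differences were 0.59 and 0.50, and without syngeneic 1 they were 1.84 and 4.34. Platelet markers had a median of -1.10 over 5 genes (adjusted p = 0.143).

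No other list passed with camera. The interferon lists had medians of -0.35 (type I, adjusted p = 0.227) and -0.08 (interferon gamma, adjusted p = 0.970), with Isg20, an interferon-induced exonuclease, at -2.33 (SE 0.70, adjusted p = 0.773; -1.31 without syngeneic 2). Inflammatory cytokines and NF-kB targets had a median of -0.21 (adjusted p = 0.365); Il1b differed by -2.45 (SE 0.71, adjusted p = 0.766; -1.55 without syngeneic 2), and Ier3, an early response gene at background in tolerant cells, was at least 2.31-fold lower (adjusted p = 0.257; 3.58-fold without syngeneic 1 and 1.49-fold without syngeneic 2), the 1 member of that list and of the immediate early list to fall when adjusted over the list alone. Lag3, an inhibitory receptor in the plasmacytoid dendritic cell list, and Nrgn in the platelet list were each the 1 member to fall when adjusted over its list alone. Both were at background in tolerant cells, and Nrgn was above it on only 1 syngeneic array, so they were at least 2.35-fold and 1.54-fold lower. Without syngeneic 2 the bound for Lag3 was 1.37-fold and Nrgn had none; without syngeneic 1 the bounds were 4.02-fold and 3.86-fold. Ribosomal proteins (-0.08 over 36 genes), glycolysis (-0.11 over 20), oxidative phosphorylation (-0.13 over 22) and cell cycle genes (-0.03 over 5) had medians near 0. The remaining medians were 0.62 for toll-like receptors and adaptors, 0.49 for dendritic cells, 0.31 for the unfolded protein response, 0.19 for complement and Fc receptors, 0.11 for MHC class I and peptide loading, 0.09 for integrins, 0.07 for chemokine receptors and 0.04 for immediate early genes. Below 0 lay TGF-beta signalling at -0.32, costimulatory ligands at -0.38, plasmacytoid dendritic cells at -0.08 and eosinophils, basophils and mast cells at -0.57. Median and mean or test differed in sign for suppressive effectors, chemokine receptors, immediate early genes, oxidative phosphorylation, MHC class I and cell cycle genes. Plasma cell markers were not tested, since only 2 members, Xbp1 (1.26, but -0.51 without syngeneic 2) and Sdc1 (at background in both groups), passed the filter.

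No named gene rose past the threshold. The 8 named genes with the smallest p among those higher in tolerant cells included RT1-DOa and Vps45, a vesicle trafficking protein, at 1.82 (SE 0.40, adjusted p = 0.470). RT1-DOa and Vps45 were above background on all 3 tolerant arrays, at least 4.74-fold (2.82-fold without tolerant 2) and 1.46-fold higher. The others, Tmem218, Fscn3, Dbh, Msx2, Lpar1 and Sytl5, were at or near background in both groups, so no size is given for them. Over all tested probes the tolerant values lay fully below the syngeneic ones for 10.4% and fully above for 9.74%, against 10% by chance in each direction.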

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

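The alternatives were chosen before the data were examined, except the lists under cyclic loess and without normalization, the background level and its bounds, and genes named outside the rule without each array, chosen after. The count of 6 probes past the threshold (limma, 721 at an unadjusted p under 0.05) was 53 with median scaling, 2 with cyclic loess, 81 without normalization (80 lower, 1 higher), 10 with a looser filter and 21 with a variance trend and robust settings. It was 0 with no filter (1759 at an unadjusted p under 0.05), 0 with array weights (562) and 0 to 91 without each array in turn (511 to 2214). With unadjusted thresholds it was 721, or 194 at p under 0.01 with at least a 2-fold difference (157 lower, 37 higher; 134 expected without the fold condition). It stayed within 1.5 times with the authors' values, other floors and a stricter filter. The cause of these shifts was not tested. The median difference of all tested probes was 0.004 as reported, -0.16 with median scaling, 0.04 with cyclic loess and -0.37 without normalization. With the replicate number as a replicate block the count was 0 (474 at an unadjusted p under 0.05). In that fit 1 tolerant array has no partner. The deviations of same-numbered samples from their group means correlated at -0.103 and 0.015. With only 2 syngeneic arrays, the syngeneic deviations mirror each other, so these values cannot show whether same-numbered samples share more than a number.

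The 7 lists called were 0 with an estimated correlation and 4 with fry, and 6 to 10 without each array; each kept its direction under all 4 scalings. Without each array the median of NK cell markers ranged from -2.87 to -2.07, of T cell markers from -2.42 to -1.97, of cytotoxic genes from -2.75 to -1.60 and of neutrophil markers from -3.01 to -2.01. Of named genes, Ccl5, Gzmk, Klrd1, Cd5 and Klre1 kept their sign throughout; Gzmk, Cd5 and Klre1 missed the threshold under cyclic loess. Ccl5 had an adjusted p from 1.7e-06 to 0.989 over its alternatives, the latter for all 5 with the replicate block, yet without each array it differed by -7.65 to -7.01, and Klrd1 by -6.49 to -6.09. No gene that changed sign had passed. Gapdh was -0.26 with median scaling, -0.47 without normalization, -0.026 with the replicate block and -0.048 to 0.28 without each array. Without each array, ranges crossing 0 were -0.59 to 0.23 for Hmox1, -0.18 to 2.34 for Cd86, -0.53 to 5.48 for Atp5f1b, -0.42 to 4.62 for Hsp90b1, -2.94 to 0.17 for Ltbp1, -0.51 to 3.02 for Xbp1, -0.31 to 1.07 for Sdc1, -0.96 to 0.15 for Ccr1, -0.35 to 3.14 for Itgam and -0.0073 to 1.28 for Actb. The cause was not tested. In all, 823 gene values kept sign and side of the threshold, 27 passed it, 28 missed it and 16 changed sign. Background limits 5 of the 6 folds past the threshold to bounds.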

Other observations

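Genes outside the naming rule, chosen after their values were seen, showed large differences that did not pass. Npy, neuropeptide Y, was at background on all 3 tolerant arrays and at 16.70 and 20.05 on the syngeneic arrays, a log2 difference of -8.81 (SE 1.09, adjusted p = 0.132), or at least 181-fold (56.7-fold without syngeneic 2 and 578-fold without syngeneic 1). S100a9, the partner of S100a8 in calprotectin, ran from 9.25 to 16.23 in tolerant cells and was 19.11 and 20.51 in syngeneic cells (adjusted p = 0.766). Lyz2, a lysozyme of myeloid cells, and Cd74, the class II invariant chain, were above background on all arrays and differed by 0.96 and 0.94; for Cd74 it was 0.27 without syngeneic 2, 0.59 without tolerant 2 and 1.61 without syngeneic 1. Cybb, a subunit of the phagocyte oxidase, differed by 2.05, but was at 9.73 on syngeneic 2 and differed by -0.44 without it.

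For the 3 patterns that follow, the tests on the combined NK and T cell markers, with and without each syngeneic array, on Ccl5 relative to other genes and on the splits of the arrays were chosen after the results were seen, as was the requirement that the erythroid value hold without either syngeneic array.

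Ccl5 fell together with genes of NK and T cells, and fewer such cells in the tolerant preparations may account for it, as a hypothesis; Nkg7, a marker of both, was at 16.71 in syngeneic and 10.34 in tolerant cells. The 30 tested NK and T cell markers had a median difference of -2.36. Of 10000 lists of random genes matched on mean signal the lowest median was -0.60. That rank decides nothing, since both marker lists were already known to be lower and random genes lack the correlation of cell markers. The median was -2.02 without genes past the threshold and -2.62 without 4 markers that myeloid cells can also carry. With genes at their bounds, NK cell markers had a median of -1.01 and T cell markers -0.88. A loss of all other cell types alike should lower B cell markers too, whose median was 1.26. That value rested on single arrays (0.14 without syngeneic 1), and tolerant 1 at -0.28 lay below syngeneic 2 at 0.20, so it does not decide. Neutrophil (-2.23) and erythroid (-1.74) markers fell too, so a wider loss, with or without B cells, stays open. For the same 30 markers, a single deviating syngeneic array is argued against only by fitted values: their median was at most -2.0 without either one (-2.42 without syngeneic 2). Many of these markers were at background in tolerant cells, so the size of that median is not measured. The test was also chosen when both lists were already known to be lower. The -4.88 reached at most by probes past the threshold decides nothing, since passing already needs both syngeneic arrays to be close. A fall of Ccl5 beyond the loss of lymphocyte genes and a fall by that loss alone cannot be told apart: it fell by 1.45 more than the mean of the other 4 genes (SE 0.50), but 0 of their 12 tolerant values were above background, so their own fall is only bounded. CD3 depletion should remove T cells, and selection for CD80 and CD86 should leave out most NK and T cells. Cell numbers after the sort, lower expression per cell and an effect of tolerance itself therefore all remain untested. The tolerant group also differed by its mismatched graft and by the JJ319 treatment, so effects of these cannot be told apart from tolerance.

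The beta globin signals, at background in tolerant cells, may reflect red cell RNA that survived lysis in the syngeneic preparations. The 4 erythroid markers other than globins had a fitted median difference of -1.49, with 3 lower. Of these 3, Gata1 (fitted at -1.48) was at background on all arrays, so no change in it is measured and the median overstates what is. The median also rested on syngeneic 2: it was -2.63 without syngeneic 1 and 0.51 without syngeneic 2, where Hbb was still at 14.49 on syngeneic 1. Red cell carryover and other sources of the globin signal therefore cannot be told apart with 2 syngeneic arrays, and no biological explanation was tested.

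The number of probes past the threshold was set against the other ways of dividing the 5 arrays into 3 and 2. The real division gave 6 and the highest of the others 0, so 1 of 10 divisions gave as many; 10 divisions are too few for a share under 0.05. At an unadjusted p under 0.05 the real division gave 721 probes, and the division of tolerant 1 and syngeneic 2 from the rest gave 1467, that of tolerant 2 and syngeneic 2 770. That points to a structure of the samples: syngeneic 2 lay at 116 on the first principal component (46.5% of the variance), with the others from -40.6 to -23.1, and tolerant 1 lay at 82.5 on the second (24.1%).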
